A study of Mus musculus with 4 samples.

How the data were processed

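Fecal 16S rRNA gene libraries of C57BL/6J mice aged 8 to 12 weeks were analysed. Mice were given ampicillin, metronidazole, neomycin, vancomycin, a mix of these 4 antibiotics, or phosphate-buffered saline (PBS) alone. Each dose held 2.5 mg of antibiotic in 100 µl and was given by mouth, into the peritoneum or into a vein, 2 doses a day on 3 full days and a last dose on day 4, with euthanasia 4 hours later. The amplified stretch was the V4 region, with 30 to 35 PCR cycles, sequenced on an Illumina MiSeq, per the labels' protocols. Read filtering, the clustering or denoising tool and the taxonomy database are not given in the sources used here.

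The 4 records of the series are the barcode and sequence read files of 2 multiplexed sequencing runs, named ok122 and SB1. They are not animals and were not compared as groups. The antibiotic, route, day and replicate number of each fecal sample came from the sample sheets that the authors deposited for the 2 runs, and the mouse was read from the start of the sample name that both days share. Of 90 mice with libraries of both days, 89 carried like annotation on both days, and 1 whose route differed was left out of the analyses within mice. All other comparisons, those between routes included, kept that mouse under the route given for the day. Antibiotic, route, day and replicate number were shared by 2 libraries of the oral mix at day 4, and both were kept as separate samples. Libraries of PBS mice were closer to the day 0 library of their own mouse (mean Bray-Curtis distance 0.296 ± 0.0952 SD, 16 pairs) than to those of other mice of the same route (0.340 ± 0.0823 SD, 70 pairs; one-sided permutation of day 0 libraries within route, 100000 resamples, p = 0.00486), and the sample name was taken to pair the days.

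The measurement is the authors' composition table, a signal scaled to 100000 per library over 488 taxa named at 7 ranks; per the file headers and the deposited values, each column is 1 fecal sample. Column sums lay between 99999.9 and 100000. The table joins 3 blocks of columns (day 0, day 4 of run ok122, day 4 of run SB1), and a taxon missing from a block leaves empty cells, 11.6% of all cells, which were read as 0. All columns of per-sample values were used. Within each library 100% of the nonzero values were whole multiples of a single step, within 0.02 reads or 1e-05 of the value, which gives the number of reads behind each value. The smallest value came to 2 reads in 183 of 198 libraries, so the recovered depth is a lower limit if all counts of a library share a factor. Recovered depth ran from 2 to 153407 reads, with a median of 13945. It was lower at day 0 (median 7289, with 24 of 107 libraries under 1000) than at day 4 (median 23566, with 4 of 91 under 1000). A taxon at 0 can lie below an upper limit of 3 reads of the library total, and such limits cover counting error only, since PCR reads are not independent molecules. The depth is recovered from scaled values and the table does not hold counts, so no count model was fitted.

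Pairs of libraries within a group were compared by a chi-square test of their recovered reads. Of 341 pairs, 2 differed by no more than sampling noise can give (p of at least 0.05), while 0 of 6802 pairs of libraries from different groups did. Each of these pairs was averaged and counted as 1 sample, which leaves 89 samples at day 4 from 91 libraries. This rule was set after the values were seen.

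Percent of reads was computed at the level of the table, at genus level (316 genera) and at family level (107 families). The Shannon index used the natural log. Each antibiotic and route at day 4 was compared with PBS of the same route, 15 comparisons, by a two-sided exact permutation test of the difference in mean Shannon index and by an exact PERMANOVA on Bray-Curtis distances, each adjusted by Benjamini-Hochberg over the 15 comparisons. Genus-level changes were tested with limma on log2(percent + 0.01) in a single fit of all day 4 samples with 1 mean per group and a moderated variance trend, over 95 genera present in at least 20% of day 4 samples. Log2 changes are on this scale and understate changes of rare genera. The threshold was an adjusted p of 0.05. Taxon lists, 13 in number, were summed per sample and tested by exact permutation, adjusted over the 15 comparisons within a list. Differences between routes in the effect on the Shannon index were tested by permuting route labels within antibiotic and within PBS samples with 100000 resamples, and in genera by the interaction contrast of the limma fit. Antibiotics were also compared in pairs within a route, day 0 groups were compared in the same way as day 4 groups, and the Bray-Curtis distance between day 0 and day 4 of a mouse was compared between antibiotic and PBS mice.

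Genera named in the text were chosen by a rule set before the data were examined. Per comparison these are the 3 with the largest rise and the 3 with the largest fall among genera past the threshold with a mean of at least 0.1% in either group. The 10 genera with the highest mean at day 0 and the taxon lists are given in every comparison. Names and their suffixes are those of the table, and an unclassified genus carries the name of the lowest rank given.

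The alternatives tried were family level, the number of taxa in place of the Shannon index, Jaccard and Aitchison distances, change from day 0 within mice, removal of taxa seen in reagents, skin and food together with unassigned taxa, pseudocounts of 0.1 and 0.001, no filter on rare genera or presence in 50% of samples, a centred log ratio, a fit of only the samples compared, taxon lists on the log2 scale, each run alone, and leaving out each sample in turn. Chosen after the data were seen were libraries of at least 1000 reads, libraries thinned to 1000 reads, run ok122 alone for genera, run as a block in the limma fit, route differences in genera among libraries of at least 1000 reads, route differences in the Shannon index without the reagent list and unassigned taxa, Burkholderia or unassigned taxa left out alone, within-mouse distances at 1000 reads or more, the sum of the class Clostridia, the number of taxa without those empty at day 0, and counting the near-identical libraries separately.

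Both kinds of test were tested on simulated data. For groups of 6 and 5 drawn from PBS means over 488 taxa with 20000 reads, the exact Shannon test called 3.5% of 200 runs with no change and 98% of runs with a 16-fold rise of the top taxon, and PERMANOVA called 6% and 99.5%. In 40 simulated data sets of the oral vancomycin comparison with 163 genera, of which 20 were changed, limma recovered 66.8% of 16-fold and 14.5% of 4-fold changes and called 0.834% of unchanged genera. In simulations of the intraperitoneal mix (168 genera) it recovered 41% of 16-fold and 16.5% of 4-fold changes and called 1.62% of unchanged genera, and of intraperitoneal ampicillin (169 genera) 19%, 0.5% and 0.423%.

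Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The sheets name individual libraries, and whether mice shared cages is not given in the sources used here.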

Results

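The composition of fecal bacteria was measured in mice given 1 of 4 antibiotics, their mix or PBS by 1 of 3 routes, with stool taken at day 0 and at day 4. Libraries of 198 fecal samples were analysed, 107 from day 0 and 91 from day 4. Run ok122 held 186 of them, all of day 0 included, and run SB1 held 12, all of day 4. After near-identical libraries were counted once, day 4 groups held 2 to 6 samples. PBS was represented by 5 oral, 5 intraperitoneal and 6 intravenous samples. Ampicillin was represented by 5, 2 and 4 samples in the same order, metronidazole by 6, 6 and 6, neomycin by 4, 6 and 4, vancomycin by 6, 5 and 6, and the mix by 4, 3 and 6. The samples are those of different mice by their names, although 2 of the oral mix share a replicate number. Exact permutation p-values rest on the samples compared alone. Limma p-values use a spread for each genus estimated over all day 4 groups. They can therefore be small where few or widely differing samples are compared.

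Day 4 libraries held between 30 and 153407 recovered reads, with a median of 23566. Of these, 4 held fewer than 1000 reads: 1 of the intraperitoneal mix (replicate 3, 30 reads), 1 of the intravenous mix (replicate 5, 65 reads), 1 of intraperitoneal neomycin (replicate 4, 70 reads) and 1 of the oral mix (replicate 2b, 556 reads). The intraperitoneal vancomycin replicates 1 and 5 differed by no more than sampling noise can give (chi-square of 1.06 per degree of freedom, p = 0.363), as did the intravenous ampicillin replicates 3 and 4 (1.29 per degree of freedom, p = 0.153). Each pair was counted as 1 sample. The next closest pair of 1 group had 2.04 per degree of freedom and the median pair had 67.4. The PBS samples of run SB1 were all intravenous, so for oral and intraperitoneal comparisons a value within a run can be had for run ok122 alone.

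At day 0 the stool was dominated by Bacteroidota. Prevotella, a genus of anaerobes of the Bacteroidaceae, made up 27.9% ± 10.5 (SD, n = 107 libraries) of reads. Genera of the Muribaculaceae, a family of anaerobes common in the mouse gut, followed, with CAG-485 at 12.5% ± 4.77, Duncaniella at 9.55% ± 3.57, unclassified Muribaculaceae at 7.90% ± 3.04 and Paramuribaculum at 6.76% ± 3.47. The 10 most abundant genera were completed by unclassified Lachnospiraceae, UBA7173, Muribaculum, COE1 and UBA3263, each between 2.28% and 6.47%. Composition was tested by an exact permutation of group labels on Bray-Curtis distances, with R2 the share of variation between groups. This test also responds to unequal spread within groups, so a shift is not told apart from greater scatter. In the 9 day 4 comparisons that passed, mean distance to the group centroid was larger with antibiotic than in PBS. By mouth it was 0.209 with vancomycin and 0.366 to 0.479 with ampicillin, neomycin and the mix, against 0.180. In the peritoneum it was 0.436 (vancomycin) and 0.524 (mix) against 0.215. By vein it was 0.414 to 0.566 against 0.219. The 10 most abundant genera are followed through each comparison, and none of them was called higher in any of the 15 comparisons.

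The first question was how each antibiotic changed the bacteria of the stool when given by mouth. Oral vancomycin, a glycopeptide that acts on the cell wall of Gram-positive bacteria and is poorly absorbed from the gut, was followed by stool made up largely of Escherichia and Borkfalkia. Escherichia_710834, a facultative anaerobe of the Enterobacteriaceae, held 49.0% ± 15.2 (SD, n = 6) of reads against 0.0838% ± 0.144 (n = 5) in oral PBS (log2 10.53, SE 1.56, adjusted p = 8.43e-08), above all PBS samples in 6 of 6 samples. Borkfalkia, of the Firmicutes, rose to 28.9% ± 14.5 from 0.136% (log2 7.92, adjusted p = 1.62e-05), and Ligilactobacillus, a lactic acid bacterium, rose to 5.61% ± 2.70 from 0.0446% (log2 6.65, adjusted p = 8.81e-08). All 10 genera most abundant at day 0 fell, among them CAG-485 to 0.0695% from 11.6% (log2 -8.51), unclassified Muribaculaceae to 0.0796% from 10.8% (log2 -8.36) and Muribaculum to 0.0540% from 5.94% (log2 -7.84). Of 41 genera of the Clostridia list, which holds named families of obligate anaerobes and leaves out those of Borkfalkia and CAG-552, 29 fell, as did 8 of 8 Muribaculaceae, with the same numbers when adjusted over the list alone.

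In all, 63 of 95 genera changed with oral vancomycin, 7 higher and 56 lower. The mean Shannon index was 1.24 ± 0.237 (SD, n = 6) against 3.00 ± 0.276 (n = 5) in PBS, a difference of -1.76 (exact permutation p = 0.00216, adjusted p = 0.0162). Composition differed from PBS (R2 of Bray-Curtis distances 0.837, exact p = 0.00216, adjusted p = 0.0108). At family level the Shannon index differed by 0.0169, which was not past the threshold. The PBS libraries had more reads (18152 to 64482) than the vancomycin libraries (1151 to 20443), and with each library thinned to 1000 reads 38 genera changed. With presence in 50% of samples required, 39 did.

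Oral ampicillin, a beta-lactam, was followed by stool in which a few genera took most reads, and not the same ones in each sample. Borkfalkia reached 39.8% ± 37.5 (SD, n = 5) against 0.136% ± 0.0868 (n = 5) in PBS (log2 5.76, SE 1.67, adjusted p = 0.00299). Burkholderia, a genus of soil and water bacteria that is also seen in reagents, held 37.2% ± 50.8 against 0.00155% (log2 6.95, adjusted p = 2.36e-05), with 89.0% and 96.6% of reads in 2 samples and at most 0.323% in the other 3. Unclassified CAG-552, of the Firmicutes, rose to 14.5% ± 19.3 from 0.0241% (log2 5.78). Of the 10 genera most abundant at day 0, 9 fell. Unclassified Muribaculaceae fell to 0.243% from 10.8% (log2 -6.65), CAG-485 to 0.316% from 11.6% (log2 -6.22) and Paramuribaculum to 0.254% from 8.41% (log2 -6.22). All 8 Muribaculaceae and 24 of 41 Clostridia-list genera fell, with the same numbers when adjusted over the list alone.

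With oral ampicillin 53 of 95 genera changed, 6 higher and 47 lower, and 37 changed within run ok122 alone. With no filter on rare genera it was 20 higher and 55 lower. Their mean Shannon index was 0.784 ± 0.340 (SD, n = 5), a difference from PBS of -2.21 (exact permutation p = 0.00794, adjusted p = 0.0238), and within run ok122 it was -2.10 (exact p = 0.0179, adjusted p = 0.107, 3 samples). For composition, R2 was 0.547 (exact p = 0.00794, adjusted p = 0.0149), and 0.603 within run ok122 (adjusted p = 0.0670). Without the reagent, skin and food list and unassigned taxa the Shannon difference was -1.15 and not past the threshold (exact p = 0.127). Left out alone in tests added after the values were seen, Burkholderia gave -1.15 (exact p = 0.127) and unassigned taxa -2.21 (exact p = 0.00794), and at family level it was -0.448 (exact p = 0.0556). In libraries thinned to 1000 reads 31 genera changed.

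After the oral mix Burkholderia was higher than in oral PBS, by widely differing amounts per sample. It held 56.4% ± 46.0 (SD, n = 4) of reads against 0.00155% ± 0.00347 (n = 5) in PBS (log2 10.24, SE 1.35, adjusted p = 4.20e-09), above all PBS samples in 4 of 4. By sample it was 91.9%, 96%, 37.8% and 0.0903%, and the library with 37.8% was that of 556 reads, in which other taxa of the reagent, skin and food list held 30.6%. The lowest, 0.0903%, was under the highest Burkholderia level of the day 0 libraries, 0.730%. No other of the 95 tested genera rose. Paramuribaculum fell to 0.149% from 8.41% (log2 -6.56), UBA3263 to 0.186% from 3.57% (log2 -6.02) and CAG-873 to 0.0552% from 1.80% (log2 -5.83), all Muribaculaceae. Of the 10 genera most abundant at day 0, 8 fell, as did 7 of 8 Muribaculaceae (8 when adjusted over the list alone) and 16 of 41 Clostridia-list genera (16 when adjusted over the list alone).

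In total 35 of 95 genera changed with the oral mix, 1 higher and 34 lower, and 33 changed within run ok122. Shannon indices averaged 1.29 ± 1.09 (SD, n = 4), a difference of -1.71 (exact permutation p = 0.00794, adjusted p = 0.0238), and -1.88 within run ok122 (exact p = 0.0476, adjusted p = 0.119, 2 samples). On Bray-Curtis distances R2 was 0.537 (exact p = 0.00794, adjusted p = 0.0149), and 0.761 within run ok122 (adjusted p = 0.102). Without mix replicate 1, 2 or 2b, 20, 22 and 23 genera changed. With any 1 of the 5 PBS samples left out the Shannon difference was -1.59 to -1.77. Its exact p was then the smallest that 4 samples against 4 allow (p = 0.0286, adjusted p = 0.0612). The Shannon difference was -0.378 (exact p = 0.270) without the reagent, skin and food list and unassigned taxa, -0.399 (exact p = 0.325) without Burkholderia alone, -1.71 without unassigned taxa alone, -0.277 at family level, -2.48 within mice (adjusted exact p = 0.0536), and the richness difference of -72.7 taxa had an adjusted exact p of 0.0595. Thinned to 1000 reads per library, 17 genera changed, and with no filter on rare genera 60 did, 18 higher and 42 lower.

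Oral neomycin, an aminoglycoside that is poorly absorbed from the gut, was followed by higher levels of Bacteroides_H, Phocaeicola and Parabacteroides, while the Bacteroidota list as a whole was at 83.3% against 85.4% in PBS and was not past the threshold. Bacteroides_H reached 15.0% ± 15.5 (SD, n = 4) against 0.553% ± 0.20 (n = 5) in PBS (log2 4.31, adjusted p = 0.0298), Phocaeicola_A_858004 reached 11% ± 20.9 against 0.0251% (log2 5.16, adjusted p = 0.0260) and Parabacteroides_B_862066 reached 2.79% ± 2.57 against 0.0453% (log2 5.37, adjusted p = 0.00789). Each was above all PBS samples in 4 of 4. Of 27 genera of the Lachnospiraceae, a family of anaerobes that includes butyrate producers, 7 fell and 1 rose. Among those that fell were COE1 to 0.00245% from 0.480% (log2 -5.17), Eubacterium_J to 0.0116% from 0.353% (log2 -3.79) and UBA3282 to 0.00184% from 0.186% (log2 -3.59). Of 41 Clostridia-list genera 12 fell and 1 rose, and none of 8 Muribaculaceae passed by limma, with the same numbers when adjusted over the list alone. COE1 was the 1 genus of the 10 most abundant at day 0 that fell.

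Oral neomycin changed 22 of 95 genera, 6 higher and 16 lower, and 12 with each mouse as its own baseline. The mean Shannon index was 2.44 ± 0.575 (SD, n = 4), a difference of -0.559 that was not past the threshold (exact permutation p = 0.0714, adjusted p = 0.107). Composition differed from PBS (R2 of Bray-Curtis distances 0.382, exact p = 0.00794, adjusted p = 0.0149), but not at family level (R2 0.189, adjusted exact p = 0.195). After thinning to 1000 reads per library, 5 genera changed.

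Oral metronidazole, a nitroimidazole active on anaerobes, left the 10 genera most abundant at day 0 without a call. Velocimicrobium, of the Lachnospiraceae, was at 0.270% ± 0.277 (SD, n = 6) and listed at 0 in all 5 PBS samples (adjusted p = 3.83e-06), and Enterocloster of the same family was at 0.404% ± 0.396 against 0.0304% ± 0.0481 (log2 3.01, SE 0.76, adjusted p = 0.00495). Prevotella was at 22.1% against 22.3% in PBS and CAG-485 at 11.9% against 11.6%. In all 4 of 95 genera changed, 2 higher and 2 lower (7 at an unadjusted p under 0.05). With each mouse as its own baseline 1 genus changed, and the log2 changes of Velocimicrobium and Enterocloster turned to -1.33 and -0.22, neither past the threshold. With presence in 50% of samples required 0 genera changed, with only the samples compared in the fit 2, with no filter 7, and thinned to 1000 reads 1. The Shannon index (3.03 ± 0.237, n = 6) differed from PBS by 0.0283 (exact permutation p = 0.892, adjusted p = 0.911), and between-group R2 of Bray-Curtis distances was 0.0961 (exact p = 0.474, adjusted p = 0.508).

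**Figure D1:**
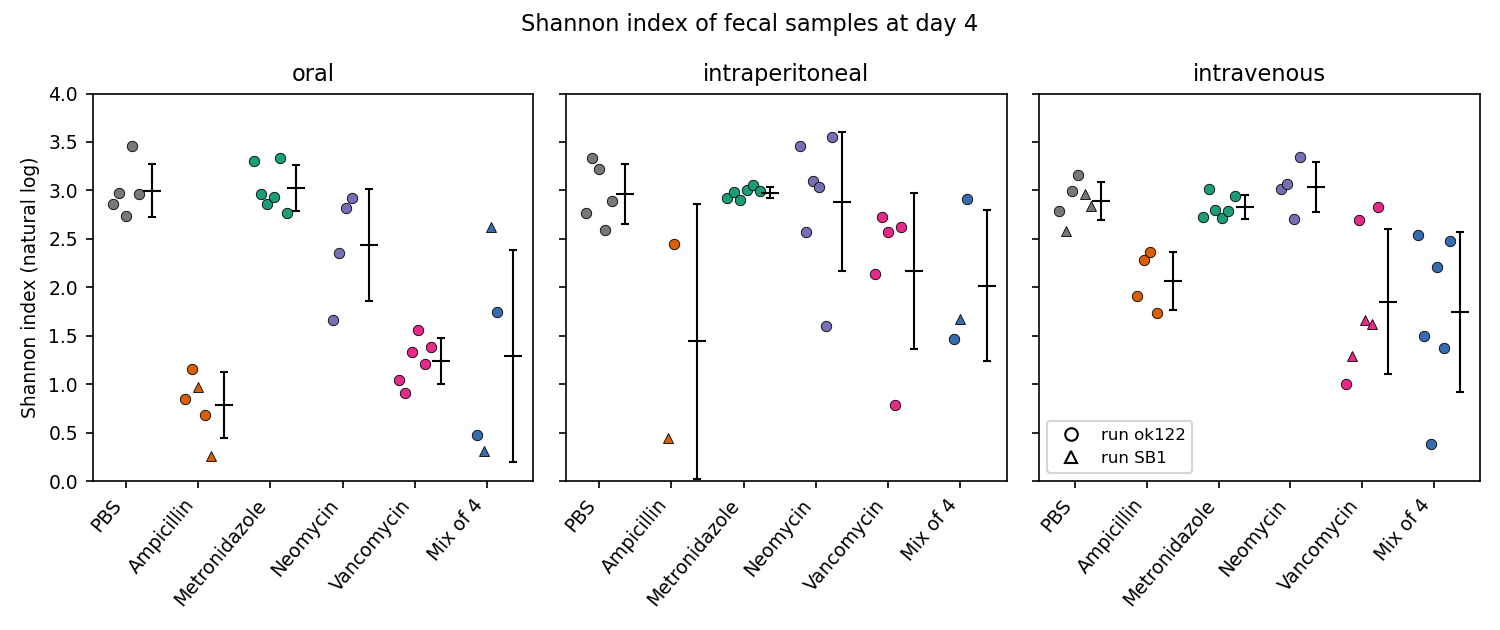
Shannon index (natural log) of each day 4 sample by antibiotic and route, with the mean and SD of each group; circles are run ok122 and triangles run SB1. Oral vancomycin samples average 1.24 and oral ampicillin samples 0.784, against 3.00 in oral PBS.

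The second question was whether antibiotics given into the peritoneum or a vein changed the stool bacteria. Intravenous vancomycin was followed by high levels of Parabacteroides, Bacteroides and Escherichia. Parabacteroides_B_862066, an anaerobe of the Tannerellaceae, reached 31.6% ± 27.6 (SD, n = 6) against 0.0325% ± 0.0223 (n = 6) in intravenous PBS (log2 8.65, SE 1.32, adjusted p = 2.06e-07), above all PBS samples in 6 of 6. Bacteroides_H rose to 17.0% ± 15.5 from 0.411% (log2 5.30, adjusted p = 0.000600), also in 6 of 6, and Escherichia_710834 to 16.3% ± 12.9 from 0.00698% (log2 8.07, adjusted p = 1.25e-05), in 5 of 6. Paramuribaculum fell to 0.00671% from 6.58% (log2 -8.65), Muribaculum to 0.538% from 7.62% (log2 -6.94) and UBA3263 to 0.336% from 2.49% (log2 -5.68). Of the 10 genera most abundant at day 0, 9 fell, and of the lists 7 of 8 Muribaculaceae (7 when adjusted over the list alone) and 20 of 41 Clostridia-list genera (23 when adjusted over the list alone) fell.

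Intravenous vancomycin changed 40 of 95 genera, 4 higher and 36 lower, 23 with each mouse as its own baseline, and 13 within run ok122, which held 3 samples of each group. The mean Shannon index was 1.85 ± 0.748 (SD, n = 6) against 2.89 ± 0.197 (n = 6), a difference of -1.04 (exact permutation p = 0.0130, adjusted p = 0.0325). Within run ok122 it was -0.802 (exact p = 0.20) and within run SB1 -1.27 (exact p = 0.10, the smallest that 3 samples against 3 allow). For composition, R2 was 0.482 (exact p = 0.00216, adjusted p = 0.0108), 0.357 within run ok122 and 0.816 within run SB1 (exact p = 0.10 in each). Without PBS replicate 1, 2, 3, 5 or 6 the Shannon difference, -0.983 to -1.06, had an adjusted exact p of 0.0510 to 0.0603, within mice it was -1.04 (adjusted exact p = 0.0835), and at family level it was 0.323.

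Intraperitoneal vancomycin was followed by a rise of Parabacteroides_B_862066 to 19.0% ± 36.3 (SD, n = 5) against 0.0420% ± 0.0411 (n = 5) in intraperitoneal PBS (log2 5.36, SE 1.45, adjusted p = 0.00382), above all PBS samples in 5 of 5 and at 83.4% in 1. Mailhella, of the sulfate-reducing family Desulfovibrionaceae, rose to 0.659% ± 1.35 from 0.00328% (log2 3.06, adjusted p = 0.00241) and Ligilactobacillus to 0.215% from 0.0504% (log2 2.81, adjusted p = 0.0387). Paramuribaculum fell to 0.0162% from 9.72% (log2 -8.79, adjusted p = 1.65e-08), and COE1 and UBA3282 were listed at 0 in all 5 samples against 0.723% and 0.258% in PBS. Of the 10 genera most abundant at day 0, 4 fell. Among the lists 12 of 41 Clostridia-list genera (12 when adjusted over the list alone) and 2 of 8 Muribaculaceae (3 when adjusted over the list alone) fell.

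Intraperitoneal vancomycin changed 24 of 95 genera, 3 higher and 21 lower, and 4 (3 higher and 1 lower) with each mouse as its own baseline, where 4 of the 6 day 0 libraries held fewer than 1000 reads. Shannon indices averaged 2.17 ± 0.803 (SD, n = 5) against 2.96 ± 0.310 (n = 5), a difference of -0.795 that was not past the threshold (exact permutation p = 0.0238, adjusted p = 0.0510). Composition differed (R2 of Bray-Curtis distances 0.315, exact p = 0.00794, adjusted p = 0.0149), but not at family level (R2 0.189, adjusted exact p = 0.102). Without vancomycin replicate 2 or 4 the Shannon difference was -0.934 and -0.910 (adjusted exact p = 0.0340 in both). It was -0.830 with libraries thinned to 1000 reads, and richness differed by -50.2 taxa (adjusted exact p = 0.0238 in both). Thinned to 1000 reads 10 genera changed, and with presence in 50% of samples required 11.

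Intravenous ampicillin was followed by rises of Phocaeicola, Parabacteroides and Escherichia and by a fall of the Clostridia list. The Bacteroidota list was at 92.1% against 90.0% in PBS and was not past the threshold. Phocaeicola_A_858004 reached 12.8% ± 18.2 (SD, n = 4) against 0.0292% ± 0.0288 (n = 6) in PBS (log2 5.89, adjusted p = 0.00282), Parabacteroides_B_862066 5.53% ± 5.51 against 0.0325% (log2 6.52, adjusted p = 0.000295) and Escherichia_710834 4.82% ± 5.25 against 0.00698% (log2 6.32, adjusted p = 0.00128). Alistipes_A_871400, an anaerobe of the Rikenellaceae, and unclassified Lachnospiraceae were listed at 0 in all 4 samples, against 1.29% and 1.02% in PBS, and Dysosmobacter of the Oscillospiraceae fell to 0.00277% from 0.998% (log2 -6.18). Of 41 Clostridia-list genera 21 fell (23 when adjusted over the list alone), as did 3 of 8 Muribaculaceae (3 when adjusted over the list alone) and 5 of the 10 genera most abundant at day 0.

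Intravenous ampicillin changed 40 of 95 genera, 5 higher and 35 lower, 42 within run ok122 and 18 with each mouse as its own baseline. Their mean Shannon index was 2.07 ± 0.300 (SD, n = 4), a difference of -0.818 (exact permutation p = 0.00476, adjusted p = 0.0238), and -0.909 within run ok122 (exact p = 0.0286, adjusted p = 0.107). On Bray-Curtis distances R2 was 0.447 (exact p = 0.00476, adjusted p = 0.0149), and 0.412 within run ok122 (adjusted p = 0.0857). The Shannon difference was -0.645 within mice (adjusted exact p = 0.136) and -0.0256 at family level, where between-group R2 of Bray-Curtis distances was 0.254 (adjusted exact p = 0.169). After thinning to 1000 reads per library, 25 genera changed.

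Intraperitoneal ampicillin had 2 samples, 1 from each run. Borkfalkia was at 55.7% ± 48.0 (SD, n = 2) against 0.142% ± 0.0918 (n = 5) in PBS (log2 8.41, SE 2.21, adjusted p = 0.00281), unclassified CAG-552 at 7.31% ± 0.194 against 0.0424% (log2 7.19, adjusted p = 0.00124) and Burkholderia at 4.28% ± 5.96, listed at 0 in all 5 PBS samples (adjusted p = 0.00281). UBA3263 was listed at 0 in both samples against 2.87% in PBS. Paramuribaculum fell to 0.0904% from 9.72% (log2 -7.58) and unclassified Lachnospiraceae to 0.0128% from 3.15% (log2 -6.78). All 10 genera most abundant at day 0, 8 of 8 Muribaculaceae and 21 of 41 Clostridia-list genera fell, with the same numbers when adjusted over the list alone. In all 48 of 95 genera changed, 7 higher and 41 lower, 20 with each mouse as its own baseline (6 higher and 14 lower) and 15 within run ok122 (8 higher and 7 lower). With no filter on rare genera it was 23 higher and 32 lower. Without replicate 2 there were 14 and without replicate 1 there were 20, with the lone sample assumed to vary like the other groups. The Shannon index was 1.44 ± 1.42 (n = 2), a difference of -1.52 at the smallest exact p that 2 samples against 5 allow (p = 0.0476, adjusted p = 0.0893), and -0.519 within run ok122 (exact p = 0.333). For composition, R2 was 0.693 (exact p = 0.0476, adjusted p = 0.0714), and 0.734 within run ok122 (exact p = 0.167). Thinned to 1000 reads per library, 19 genera changed.

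The intravenous mix was followed by a fall of Muribaculaceae. Paramuribaculum fell to 0.10% ± 0.188 (SD, n = 6) from 6.58% ± 3.28 (n = 6) in PBS (log2 -7.12, SE 1.11, adjusted p = 6.52e-07), CAG-485 to 0.552% from 15.0% (log2 -6.43) and UBA3263 to 0.230% from 2.49% (log2 -5.48), each below all PBS samples in 6 of 6. Parabacteroides_B_862066 rose to 3.28% ± 4.38 from 0.0325% (log2 3.97, adjusted p = 0.0105) and unclassified CAG-552 to 0.949% ± 1.31 from 0.0210% (log2 3.23, adjusted p = 0.0160). Streptococcus was at 7.49% ± 18.2 against 0.0238% (log2 2.77, adjusted p = 0.0275), with 44.6% in the library of 65 reads, and was not past the threshold among libraries of at least 1000 reads. Of the lists 7 of 8 Muribaculaceae (8 when adjusted over the list alone) and 20 of 41 Clostridia-list genera (22 when adjusted over the list alone) fell, as did 8 of the 10 genera most abundant at day 0.

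The intravenous mix changed 41 of 95 genera, 5 higher and 36 lower, and 38 within run ok122 (1 higher and 37 lower). With no filter on rare genera it was 15 higher and 35 lower, and with only the samples compared in the fit 0 higher and 35 lower. The mean Shannon index was 1.75 ± 0.828 (SD, n = 6), a difference of -1.14 (exact permutation p = 0.00216, adjusted p = 0.0162), and -1.23 within run ok122 (exact p = 0.0357, adjusted p = 0.107). On Bray-Curtis distances R2 was 0.309 (exact p = 0.00216, adjusted p = 0.0108), and 0.246 within run ok122 (adjusted p = 0.102). The Shannon difference was 0.253 at family level (adjusted exact p = 0.714), and the richness difference of -43.2 taxa was not past the threshold (adjusted exact p = 0.0714). Thinned to 1000 reads per library, 24 genera changed.

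Intraperitoneal mix samples, 3 in number, had lower Paramuribaculum (0.837% ± 1.41, SD, n = 3, against 9.72% ± 6.12, n = 5; log2 -6.19, adjusted p = 0.00267), CAG-485 (7.12% ± 12.3 against 17.2%; log2 -6.16, adjusted p = 0.00601) and unclassified Muribaculaceae (2.17% ± 3.72 against 10.6%; log2 -6.10, adjusted p = 0.00390). None of the 95 tested genera rose. Of the lists 6 of 8 Muribaculaceae and 15 of 41 Clostridia-list genera fell, with the same numbers when adjusted over the list alone, as did 7 of the 10 genera most abundant at day 0. By limma 28 of 95 genera fell, and 0 changed without the library of 30 reads (replicate 3, run SB1). Among libraries of at least 1000 reads, which leaves out that library and 3 of other groups, 14 changed, 2 higher and 12 lower, with 12 shared with the 28. There were 3 without replicate 1, 5 with each mouse as its own baseline and 0 within run ok122. The Shannon difference of -0.947 was not past the threshold (exact permutation p = 0.0714, adjusted p = 0.107), and it was -0.776 within run ok122 (exact p = 0.190). Between-group R2 of Bray-Curtis distances was 0.325 (exact p = 0.0179, adjusted p = 0.0298), and 0.346 within run ok122, which leaves out replicate 3 (exact p = 0.0952). Without mix replicate 1 or 2 R2 was 0.350 and 0.534, at the smallest exact p that 2 samples against 5 allow (p = 0.0476, adjusted p = 0.0714). Without PBS replicate 4 or 5 R2 was 0.319 and 0.307 (adjusted exact p = 0.0857). R2 was 0.411 at family level (adjusted exact p = 0.134) and 0.350 thinned to 1000 reads, where 1 genus changed, which was higher and not among the 28. Richness, which was not thinned, differed by -62 taxa (adjusted exact p = 0.0446). The library of 30 reads held 6 taxa and the other mix samples 56 and 100, against a PBS mean of 116. With a pseudocount of 0.1 16 genera changed, and with only the samples compared in the fit 2 did. With no filter on rare genera 28 changed, 17.9% of them higher, and a centred log ratio gave 2 higher and 24 lower.

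Intraperitoneal and intravenous metronidazole and neomycin left the 10 genera most abundant at day 0 without a call. With intraperitoneal metronidazole Enterocloster rose to 0.433% ± 0.628 (SD, n = 6) from 0.0105% ± 0.0234 (n = 5; log2 3.63, SE 0.76, adjusted p = 0.000754) and Velocimicrobium to 0.247% ± 0.383 from 0.00846% (log2 2.75, adjusted p = 0.00997). With intravenous metronidazole Velocimicrobium fell to 0.0130% from 0.165% (log2 -2.37, adjusted p = 0.0353) and UBA6985, of the order RF39, to 0.00669% from 0.174% (log2 -2.36, adjusted p = 0.0114), and with intravenous neomycin UBA6985 fell to 0.00139% (log2 -2.72, adjusted p = 0.00724). In these 3 calls 0 samples lay below all PBS samples. These were all the calls among the 95 tested genera, 2 with intraperitoneal metronidazole (12 at an unadjusted p under 0.05), 2 with intravenous metronidazole (9 unadjusted) and 1 with intravenous neomycin (8 unadjusted). For intraperitoneal neomycin limma called 0 (7 unadjusted). With each mouse as its own baseline 0 genera changed in each of these comparisons, and 0 with presence in 50% of samples required. With no filter on rare genera intravenous neomycin gave 10, 9 higher and 1 lower, and intravenous metronidazole 0. Thinned to 1000 reads intravenous metronidazole gave 1 genus, higher and not among the 2, and intravenous neomycin 0.

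These small counts moved with single samples. Without metronidazole replicate 1 or 4 the intraperitoneal count was 1. The intravenous metronidazole count was 1 without metronidazole replicate 1, 2, 3, 4 or 5 or PBS replicate 5 or 6, 0 without PBS replicate 2 and 4 without PBS replicate 3. The intravenous neomycin count was 0 without PBS replicate 2 and 2 without PBS replicate 3. Within run ok122 intravenous metronidazole and neomycin each gave 1. The Shannon index differed from PBS by 0.0149 with intraperitoneal metronidazole, -0.0788 with intraperitoneal neomycin, -0.0558 with intravenous metronidazole (-0.147 within run ok122) and 0.149 with intravenous neomycin (0.0577 within run ok122), with adjusted exact p-values of 0.911, 0.911, 0.695 and 0.455. R2 of Bray-Curtis distances was 0.161, 0.0702, 0.147 (0.150 within run ok122) and 0.115 (0.134 within run ok122), with adjusted exact p-values of 0.159, 0.861, 0.206 and 0.385. With Jaccard distances intravenous neomycin passed (R2 0.161, adjusted exact p = 0.0429).

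**Figure D2:**
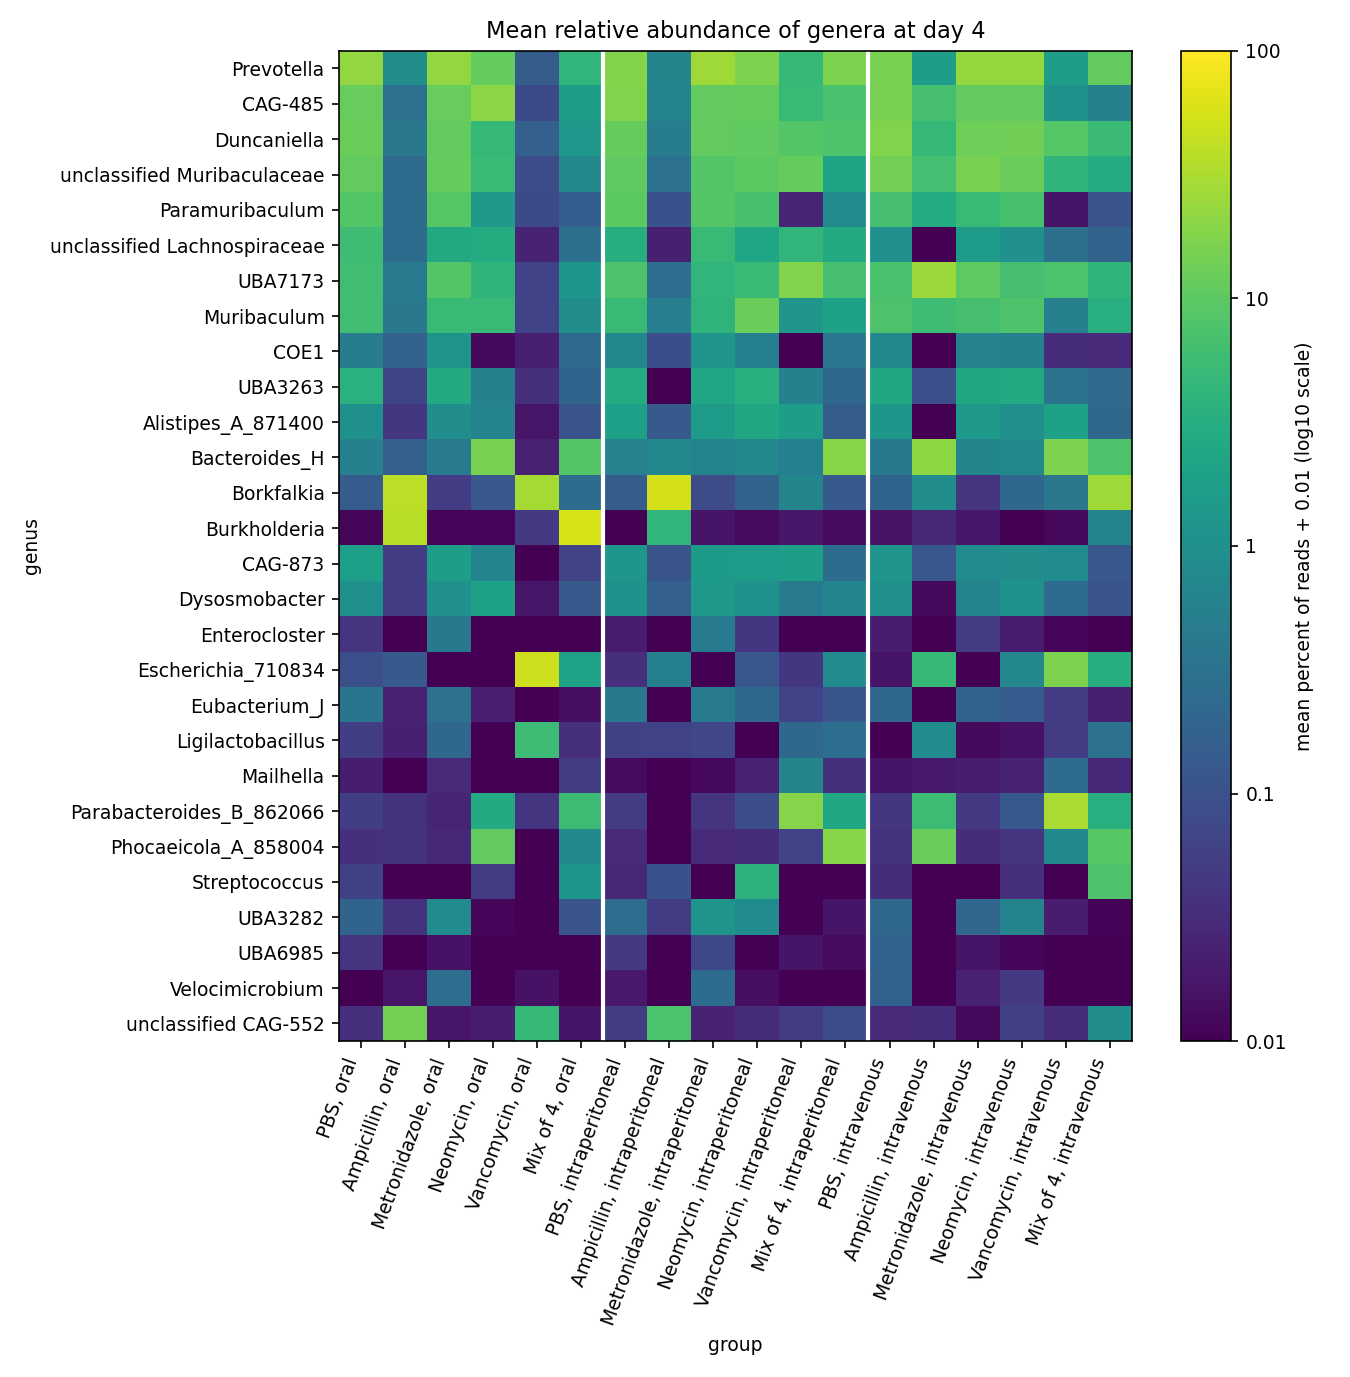
Mean percent of reads of the named genera in each day 4 group, in rows by genus and columns by antibiotic and route, with the colour on a log scale. Muribaculaceae genera such as CAG-485 are at 11.6% in oral PBS and 0.0695% after oral vancomycin, while Escherichia_710834 goes from 0.0838% to 49.0%.

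Summed per sample, the taxon lists passed the threshold in 19 of the tests. The families of the Clostridia list fell in 5 of 15 comparisons, with oral vancomycin (0.0566% ± 0.0583, SD, n = 6, against 12.4% ± 10.6, n = 5; adjusted exact p = 0.0162), and also with oral ampicillin (0.894%) and intravenous ampicillin, vancomycin and the mix (0.00277%, 1.79% and 0.972% against 7.14%). The class Clostridia as a whole, which holds Borkfalkia and CAG-552 and was summed after the values were seen, passed in 0 of 15 by exact permutation (5 at an unadjusted p under 0.05, lowest adjusted p = 0.0758). It was at 33.8% ± 8.58 (SD, n = 6) with oral vancomycin and 56.0% ± 48.9 (n = 5) with oral ampicillin against 13.5% ± 10.7 (n = 5), and at 0.989%, 2.34% and 29.5% with intravenous ampicillin, vancomycin and the mix against 8.29%. Muribaculaceae fell in 5, to 2.12%, 0.505% and 6.48% with oral ampicillin, vancomycin and the mix against 60.6% in PBS (adjusted exact p = 0.0298 in each), and to 23.3% and 16.7% with intravenous vancomycin and the mix against 71.7%. Proteobacteria, the phylum of Escherichia and Burkholderia, rose in 5, to 58.2% with oral vancomycin, 58.7% with the oral mix and 1.58% with oral neomycin against 0.189%, to 16.7% with intravenous vancomycin against 0.221% and to 1.80% with intraperitoneal vancomycin against 0.130%. With the oral mix Burkholderia, which is also seen in reagents, made up 56.4% of reads. Enterobacteriaceae rose with oral vancomycin to 49.1% from 0.0861% (adjusted exact p = 0.0325), and Bacteroidota fell to 0.71% from 85.4%. Actinobacteria and Tenericutes with RF39, bacteria that lack a cell wall, were listed at 0 in all 6 oral vancomycin samples against 0.0485% and 0.111% in PBS (adjusted exact p = 0.0325 in both), where 0 allows up to 0.261% in the shallowest library and 0.00401% over the group.

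Lactobacillaceae, Erysipelotrichia, Verrucomicrobia including Akkermansia, Enterococcaceae with Streptococcaceae, and the reagent, skin and food list passed in 0 of 15 comparisons by exact permutation. The lowest unadjusted exact p was 0.00433 for Lactobacillaceae (oral vancomycin, 5.63% against 0.0568%), 0.127 for Erysipelotrichia (oral neomycin, 0.0191% against 0.00322%), 0.0159 for Verrucomicrobia (oral neomycin, 5.64% against 0.0285%), 0.0152 for Enterococcaceae with Streptococcaceae and 0.00794 for the reagent list (oral mix, 64.5% against 0.00155%). By limma, single genera of some lists passed. Of 3 Lactobacillaceae genera 1 rose with oral and intraperitoneal vancomycin, intravenous ampicillin and the intravenous mix, and adjusted over the list alone 1 also rose with intraperitoneal metronidazole and intravenous neomycin and 1 fell with the intravenous mix. Streptococcus was the 1 tested genus of its list and rose with the intravenous mix, and Burkholderia, the 1 tested genus of the reagent list, rose with oral and intraperitoneal ampicillin and the oral mix. The 1 tested Verrucomicrobia genus passed in 0 of 15 comparisons by limma and rose with oral neomycin when adjusted over the list alone, and no genus of Erysipelotrichia was tested. Of 4 Proteobacteria genera 2 rose with oral vancomycin and 1 each with oral ampicillin, neomycin and the mix, intraperitoneal ampicillin, and intravenous ampicillin and vancomycin, with the same numbers when adjusted over the list alone. Of 3 Tenericutes and RF39 genera 2 fell with oral ampicillin and oral vancomycin and 1 with each of the 5 antibiotic treatments by vein, with the same numbers when adjusted over the list alone. By vein the fall was in the family UBA660, at 0.194% in the shared intravenous PBS group and 0.0562% in oral PBS. Whether that control gave the fall was not tested. Pelethenecus of the Anaeroplasmataceae, chosen after its values were seen, is placed by the table in the order Acholeplasmatales, which that list does not name, and it rose with oral (2.87% against 0.135%) and intraperitoneal ampicillin (2.92% against 0.128%). Of 17 Bacteroidota genera 13, 14 and 12 fell and 0 rose with oral ampicillin, vancomycin and the mix, and 1 fell and 3 rose with oral neomycin. In the peritoneum 13 fell with ampicillin, 4 fell and 1 rose with vancomycin (5 and 1 when adjusted over the list alone) and 9 fell with the mix (10 fell and 1 rose when adjusted over the list alone). By vein 8 fell and 3 rose with ampicillin, 10 fell and 2 rose with vancomycin, and 10 fell and 1 rose with the mix. Of 2 Actinobacteria genera 1 rose with oral and intraperitoneal ampicillin, and 1 fell with oral vancomycin. When adjusted over the list alone the fall with oral vancomycin did not pass, while 1 fell with oral ampicillin, intraperitoneal metronidazole and vancomycin, and intravenous vancomycin and the mix.

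The list of segmented filamentous bacteria matched 0 taxa. Percentages of a whole rise when others fall. A centred log ratio, which measures each genus against the mean of the rest, moved the median log2 change of all genera by 0.59 with oral ampicillin, 0.31 with oral neomycin, 0.75 with oral vancomycin, 0.51 with the oral mix, 0.48 with intraperitoneal ampicillin, 0.31 with intraperitoneal vancomycin and 0.48 with the intraperitoneal mix. It moved it by 0.54, -0.19, 0.45 and 0.38 with intravenous ampicillin, neomycin, vancomycin and the mix. The medians before were -1.86, -1.02, -1.96, -1.45, -1.90, -1.01, -1.47, -1.65, 0.45, -1.14 and -1.46 in the same order.

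Mice could be compared with themselves. The Bray-Curtis distance between day 0 and day 4 of a mouse was 0.985 ± 0.0113 (SD, n = 6) with oral vancomycin, 0.960 ± 0.0347 (n = 5) with oral ampicillin and 0.962 ± 0.0212 (n = 3) with the oral mix, against 0.295 ± 0.111 (n = 5) in oral PBS. It was 0.855 ± 0.195 with intravenous vancomycin, 0.822 ± 0.184 with the intravenous mix and 0.793 ± 0.142 with intravenous ampicillin, against 0.343 ± 0.0553 (n = 6) in PBS. This distance was larger than in PBS mice of the same route in 9 of 15 comparisons by exact permutation, 4 oral, 2 intraperitoneal and 3 intravenous, but in 0 with Jaccard distances. Among mice with at least 1000 reads on both days it was larger in 3, all intravenous, and in 3 with those libraries thinned to 1000 reads. That left 1 to 6 antibiotic and 3 to 5 PBS mice per group, with 0.985 against 0.284 for oral vancomycin (4 and 3 mice, adjusted exact p = 0.107), 0.674 ± 0.249 (SD, n = 2) against 0.241 for intraperitoneal vancomycin (adjusted exact p = 0.119) and 0.393 (1 mouse) for the intraperitoneal mix, which was at 0.720 with all 3 mice. For metronidazole it was 0.276, 0.207 and 0.330 by the 3 routes against 0.295, 0.241 and 0.343 in PBS. The change in Shannon index within a mouse was past the threshold in 3 of 15, oral ampicillin (-2.53), oral vancomycin (-2.19) and the intravenous mix (-1.40).

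The groups were also compared before treatment. At day 0 composition differed from PBS in 1 of 15 comparisons, that of mice later given the mix into a vein (R2 of Bray-Curtis distances 0.277, exact p = 0.00216, adjusted p = 0.0325), in 3 at an unadjusted p under 0.05, and in 0 with Jaccard distances (4 unadjusted). The day 0 Shannon index differed in 0 of 15 by exact permutation (1 unadjusted). In the 16 PBS mice with both days, Muribaculaceae were at 55.0% ± 10.7 (SD) at day 0 and 66.3% ± 14.2 at day 4 (exact sign-flip p = 0.00699, adjusted p = 0.0466). Enterococcaceae with Streptococcaceae were listed at 0 at day 0 and at 0.0331% at day 4 (adjusted exact p = 0.0195). The number of taxa went from 70.2 ± 35.9 to 117 ± 27.8 (exact p = 0.000610, adjusted p = 0.0122), higher in 14 of 16 mice. At 1000 reads per library the number of taxa was 56.3 and 63.2 in 13 mice (exact p = 0.117). Without the 49 taxa empty in all day 0 libraries it went from 70.2 to 116 unthinned (exact p = 0.000610). Day 0 and day 4 columns come from blocks of the table that list different taxa, so day and block cannot be told apart.

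The third question was whether the effect of an antibiotic differed by route, tested as an interaction. Oral vancomycin differed from intravenous vancomycin in 9 genera and from intraperitoneal vancomycin in 12. Relative to PBS of the route, Bacteroides_H (log2 -10.52, SE 1.89) and Parabacteroides_B_862066 (log2 -9.40) were lower by mouth than by vein, while Borkfalkia (log2 7.91) and Ligilactobacillus (log2 5.15) were higher. Escherichia_710834 was higher by mouth than by the peritoneum (log2 10.38, SE 2.25, adjusted p = 0.00137). Ampicillin differed in 7 genera between mouth and vein, with Burkholderia (log2 6.65), unclassified CAG-552 (log2 5.82) and Pelethenecus (log2 4.91) higher by mouth and Parabacteroides_B_862066 (log2 -7.41), Bacteroides_H (log2 -6.71) and Ligilactobacillus (log2 -6.23) lower. Between peritoneum and vein 4 genera differed, Borkfalkia (log2 9.65) and unclassified CAG-552 (log2 7.23) among the 3 that were higher by the peritoneum. The peritoneal ampicillin group held 2 samples, 1 from each run, so these calls lean on the spread estimated over all day 4 groups.

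Oral neomycin differed from intravenous neomycin in 12 genera, 11 of them lower by mouth, among them UBA3282 (log2 -5.68, SE 1.45) and COE1 (log2 -4.98). The mix differed in 1 genus, Burkholderia, which was higher by mouth than by the peritoneum (log2 9.91, SE 2.00, adjusted p = 0.000353) and than by vein (log2 8.57, SE 1.79, adjusted p = 0.000653). Metronidazole differed in Velocimicrobium, higher by mouth (log2 6.55, SE 0.98) and by the peritoneum (log2 5.13, SE 0.98) than by vein. Velocimicrobium was at 0.165% in intravenous PBS and 0 in oral PBS. Through that control it also counts among genera differing between mouth and vein with ampicillin (0.00716% and 0) and vancomycin (0.00594% and 0). With each mouse as its own baseline, its oral metronidazole change was -1.33, and intraperitoneal and intravenous metronidazole changed 0 genera. Route differences were not examined on that baseline. In the other 6 pairs of routes limma called 0 genera, with 2 to 20 at an unadjusted p under 0.05. Among libraries of at least 1000 reads there were 12 for oral against intravenous ampicillin, 11 for oral against intraperitoneal neomycin and 2 for intraperitoneal against intravenous vancomycin. Of 15 pairs of routes the Shannon effect differed in 1, oral against intravenous ampicillin (-1.40, two-sided permutation p = 0.00302, adjusted p = 0.0453). Without the reagent, skin and food list and unassigned taxa that difference was -0.334 (permutation p = 0.588, adjusted p = 0.768), and 0 of 15 pairs passed (1 at an unadjusted p under 0.05). Without Burkholderia alone it was -0.328 (permutation p = 0.599).

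**Figure D3:**
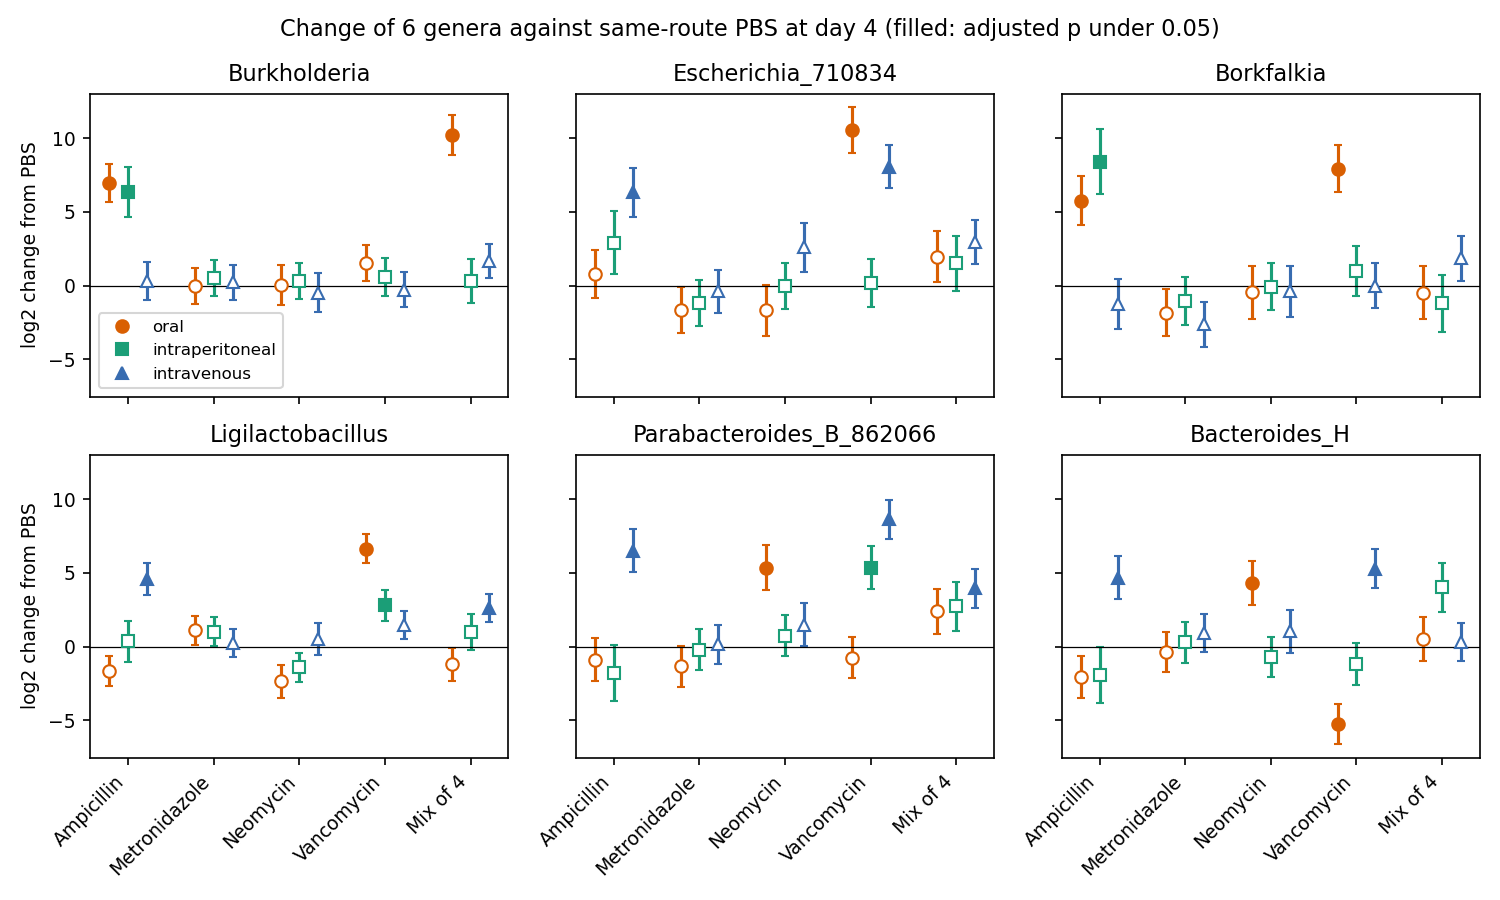
Log2 change from PBS of the same route, with the standard error, for genera named in the text by antibiotic and route; filled markers have an adjusted p under 0.05. Burkholderia after the mix is at 10.24 by mouth and 1.67 by vein.

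Antibiotics were compared with each other within a route. By the exact permutation test composition differed for 8 of 10 pairs by mouth, 4 of 10 in the peritoneum and 6 of 10 by vein, and the Shannon index for 5, 1 and 3 pairs. Whether these numbers differ between routes was not tested.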

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

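The tests of Burkholderia, route differences in the Shannon index with taxa left out, route differences in genera among libraries of at least 1000 reads, the unthinned number of taxa without those empty at day 0, the use of each mouse as its own baseline to weigh the day 0 difference of the intravenous mix, and the counts over other splits were tests chosen only after the result was seen, while the other tests of route differences and of the number of taxa were set before. The effect of an antibiotic differed between routes, by a test of the difference itself, in 10 results. The effect of ampicillin on the Shannon index differed by -1.40 between mouth and vein (permutation p = 0.00302, adjusted p = 0.0453), but by -0.334 without the reagent list and unassigned taxa (permutation p = 0.588) and by -0.328 without Burkholderia alone (permutation p = 0.599), so it depends on Burkholderia. Effects on genera differed for 7 genera between mouth and vein and 4 between peritoneum and vein with ampicillin, whose peritoneal group held 2 samples. For metronidazole it was 1 genus between mouth and vein and 1 between peritoneum and vein. For neomycin it was 12 between mouth and vein, and for vancomycin 12 between mouth and peritoneum and 9 between mouth and vein. For the mix it was 1 between mouth and peritoneum and 1 between mouth and vein. In 16 groups of 4 to 6 samples no Shannon index was called apart by a Dixon test, which sets the gap to the next value against the group's range. That test has little power in groups so small. Intraperitoneal vancomycin replicate 3 was at 0.789 against 2.13 to 2.72 in the others. Intraperitoneal neomycin replicate 4, of 70 reads, was at 1.60 against 2.57 to 3.55.

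Burkholderia took 89.0% and 96.6% of reads in 2 of 5 oral ampicillin libraries and 91.9% and 96% in 2 of 4 oral mix libraries. A difference between the sequencing runs was argued against, since in the run where its highest level was smaller it still reached 91.9%. Low read yield alone was argued against, since in 25 libraries under 1000 reads of mice not yet or never given ampicillin or the mix it reached at most 0.440%. Growth of Burkholderia under the oral drug would fit the difference between mouth and vein (log2 6.65 for ampicillin, the smaller of both), but reagent DNA in samples with little bacterial DNA would also give it. That explanation may hold or not: the median of other reagent taxa was 0.0300%, the DNA amount and blanks were not analysed here, and it stays open.

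In PBS mice the number of taxa went from 70.2 at day 0 to 117 at day 4. At 1000 reads per library the difference was 6.92 taxa (exact sign-flip p = 0.117), so a difference in depth could account for most of it. Taxa listed for 1 of the joined blocks alone were argued against as the whole cause, since without the 49 taxa empty in all day 0 libraries the unthinned difference was still 46 taxa (SD 46.8, exact p = 0.000610, higher in 14 of 16 mice). At 1000 reads leaving them out gave 6.85 taxa (exact p = 0.118), which decides nothing, as the difference was not past the threshold before. No biological explanation was tested.

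Mice of the intravenous mix differed from PBS mice at day 0 already. With each mouse as its own baseline 44 genera changed, against 41 at day 4 alone, which argues against a difference present at day 0 as the whole cause. Whether part of the day 4 difference came from day 0 was not tested.

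The count of changed genera was set against other splits of the same samples, at most 100 for each comparison with the real one included. Such a count does not weigh which genera were called or how far they moved. With at most 100 splits and no adjustment over the comparisons, such counts cannot exclude chance, and they do not address shared cages. They were taken to argue against chance where under 5% of splits gave as many. That was so for oral ampicillin (53 genera, 1 of 100 splits, highest other 27), oral neomycin (22, 1 of 100, highest other 19), oral vancomycin (63, 1 of 100, highest other 52), the oral mix (35, 1 of 100, highest other 30), intraperitoneal vancomycin (24, 1 of 100, highest other 17), intravenous ampicillin (40, 1 of 100, highest other 29), intravenous vancomycin (40, 2 of 100, highest other 50) and the intravenous mix (41, 1 of 100, highest other 28). For the intraperitoneal mix (28 genera) 2 of 56 splits gave as many, but the highest other gave 29 and 0 genera changed without the library of 30 reads, so this is not taken to argue against chance. The split with 29 genera placed the 1 library of run SB1, which is that of 30 reads, with another mix sample and a PBS sample. The split with 50 genera set 1 vancomycin and 5 PBS samples against the rest, nearly the mirror of the real one. Chance was not argued against for oral metronidazole (4, 7 of 100, highest other 6), intraperitoneal metronidazole (2, 43 of 100, highest other 5), intravenous metronidazole (2, 15 of 100, highest other 6) and intravenous neomycin (1, 39 of 100, highest other 3). For intraperitoneal neomycin (0 genera, 100 of 100 splits, highest other 8) every split gives at least 0, so the count says nothing on chance. The 2 samples of intraperitoneal ampicillin were too few for this count.

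For differences between routes few splits gave as many for oral against intravenous ampicillin (7 genera, 2 of 100 splits, highest other 7), oral against intravenous neomycin (12, 1 of 100, highest other 11), oral against intraperitoneal vancomycin (12, 2 of 100, where the highest other, 18, is more than the real count) and oral against intravenous vancomycin (9, 1 of 100, highest other 4). Another split reached the real count for that ampicillin pair and passed it for oral against intraperitoneal vancomycin. What those splits held was not examined, so chance is less clearly argued against there. Chance was not argued against for the count of metronidazole by mouth against vein (1, 27 of 100, highest other 5) or peritoneum against vein (1, 40 of 100, highest other 5). Nor was it for that of the mix by mouth against peritoneum (1, 30 of 100, highest other 5) or vein (1, 22 of 100, highest other 4). A split counts here if it calls any genus, so this does not test the changes of Velocimicrobium and Burkholderia themselves. Where 0 genera differed, 100 of 100 splits give as many by construction and the count says nothing on chance. That is so for metronidazole and neomycin by mouth against peritoneum (highest other 8 in both), and for neomycin, vancomycin and the mix by peritoneum against vein (highest other 3, 16 and 5). Pairs of routes with intraperitoneal ampicillin, which had 2 samples, were not set against splits.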

How the results depend on the processing

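Libraries of at least 1000 reads, thinning to 1000 reads, run as a block, genera within run ok122, near-identical libraries counted separately, the class Clostridia as a whole and route differences in the Shannon index without the reagent list and unassigned taxa were tests chosen only after the result was seen, and the others were planned. Of 87 PERMANOVA results under an alternative 73 kept their side of the threshold, as did 80 of 102 Shannon results. Of named genera 1753 of 1930 values did, each a genus in 1 comparison under 1 alternative. A change of sign with neither value past counted as kept. These totals include results not past to begin with, those of 6 of 15 comparisons for PERMANOVA and 9 of 15 for the Shannon index. Of Shannon results 16 lost the call, 3 changed sign and lost it, and 3 gained one. Of PERMANOVA results 13 lost the call and 1 gained one. Of counts, 107 of 155 of changed genera and 12 of 15 of genera differing by route stayed within 1.5 times. Aitchison distances left all 15 PERMANOVA comparisons on their side of the threshold, 9 past and 6 not. The taxon lists gave 19 calls on both scales, but the class Clostridia as a whole gave 0 where the list of its families gave 5. The cause was not tested where none is given.

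For the Shannon index, family level gave -0.448 with oral ampicillin, -0.277 with the oral mix and -0.0256 with intravenous ampicillin, no longer past the threshold, and turned oral vancomycin to 0.0169, intravenous vancomycin to 0.323 and the intravenous mix to 0.253. Without the reagent list and unassigned taxa it was -1.15 with oral ampicillin and -0.378 with the oral mix. Richness lost the call for the oral mix (-72.7) and the intravenous mix (-43.2) and gained one for intraperitoneal vancomycin (-50.2) and the intraperitoneal mix (-62). The last includes the library of 30 reads, which held 6 taxa. Within mice the oral mix (-2.48), intravenous ampicillin (-0.645) and intravenous vancomycin (-1.04) were not past, and thinning brought intraperitoneal vancomycin past (-0.830). For the oral mix within mice the exact p was the smallest that 3 mice against 5 allow (p = 0.0179). Within run ok122, with fewer samples, none of -2.10 (oral ampicillin), -1.88 (oral mix), -0.909, -0.802 and -1.23 (intravenous ampicillin, vancomycin and mix) was past, nor was -1.27 within run SB1 (intravenous vancomycin). Oral ampicillin, the oral mix and intravenous ampicillin were at the smallest exact p that their samples allow (p = 0.0179, 0.0476 and 0.0286), as was run SB1 (p = 0.10). There the loss of the call says nothing on the effect.

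For PERMANOVA, family level gave R2 0.189 with oral neomycin, 0.189 with intraperitoneal vancomycin, 0.411 with the intraperitoneal mix and 0.254 with intravenous ampicillin, none past. Run ok122 gave 0.603 and 0.761 (oral ampicillin and mix), 0.346 (intraperitoneal mix), 0.412, 0.357 and 0.246 (intravenous ampicillin, vancomycin and mix) and run SB1 0.816 (intravenous vancomycin), none past with fewer samples. The intraperitoneal mix had 0.346 among libraries of at least 1000 reads and 0.350 thinned. Jaccard distances brought intravenous neomycin past (0.161), and gave 0 in place of 1 difference at day 0 and 0 in place of 9 within mice, where libraries of at least 1000 reads gave 3 and thinning gave 3, with fewer mice. Richness gave 2 route differences in place of 1, and leaving out the reagent list and unassigned taxa gave 0.

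Thinning gave 31, 1, 5, 38 and 17 changed genera for oral ampicillin, metronidazole, neomycin, vancomycin and the mix, 19, 10 and 1 for intraperitoneal ampicillin, vancomycin and the mix, and 25, 1, 0 and 24 for intravenous ampicillin, metronidazole, neomycin and the mix. The 1 of the intraperitoneal mix and the 1 of intravenous metronidazole were higher and not among the 28 and 2 genera called without thinning, all of which were lower. With mouse as replicate block it was 1 and 12 for oral metronidazole and neomycin, 20, 0, 4 and 5 for intraperitoneal ampicillin, metronidazole, vancomycin and the mix, and 18, 0, 0 and 23 for intravenous ampicillin, metronidazole, neomycin and vancomycin, and with oral metronidazole it turned Velocimicrobium to -1.33 and Enterocloster to -0.22. Presence in 50% of samples, with fewer genera, gave 0 and 39 for oral metronidazole and vancomycin, 0 and 11 for intraperitoneal metronidazole and vancomycin, and 0 and 0 for intravenous metronidazole and neomycin. No filter gave 7 and 60 for oral metronidazole and the mix and 0 and 10 for intravenous metronidazole and neomycin, where 9 of the 10 were higher and the 1 with the filter lower. Only the samples compared gave 2 for oral metronidazole, 1 and 2 for intraperitoneal metronidazole and the mix, and 0 and 0 for intravenous metronidazole and neomycin. The 1 of intraperitoneal metronidazole was not among the 2 genera called in the fit of all samples. A pseudocount of 0.1 gave 4, 16 and 1 for intraperitoneal metronidazole, the intraperitoneal mix and intravenous metronidazole, and 0.001 gave 0 for the last. Run ok122 gave 15, 0, 1 and 13 for intraperitoneal ampicillin, the intraperitoneal mix, intravenous metronidazole and intravenous vancomycin, and run as a block 1 for intravenous metronidazole. Libraries of at least 1000 reads gave 14 for the intraperitoneal mix, and between routes 12 for oral against intravenous ampicillin, 11 for oral against intraperitoneal neomycin and 2 for intraperitoneal against intravenous vancomycin. The centred log ratio gave 2 for intravenous neomycin. It moved the split of intraperitoneal vancomycin from 3 higher and 21 lower to 5 and 17, from 12.5% to 22.7% higher, by 10.2 points.

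Leaving out each sample in turn, the Shannon difference lay between -2.31 and -2.08, -0.0378 and 0.144, -0.720 and -0.299, -1.82 and -1.64, and -2.15 and -1.38 for oral ampicillin, metronidazole, neomycin, vancomycin and the mix. In the same order it was -2.52 to -0.519, -0.0772 to 0.108, -0.212 to 0.179, -0.934 to -0.451 and -1.39 to -0.672 in the peritoneum, and -0.915 to -0.705, -0.116 to -0.00236, 0.0438 to 0.258, -1.23 to -0.867 and -1.30 to -0.869 by vein. R2 was 0.520 to 0.629, 0.0898 to 0.131, 0.364 to 0.543, 0.823 to 0.882 and 0.495 to 0.782 by mouth, 0.686 to 0.761, 0.134 to 0.224, 0.0588 to 0.105, 0.294 to 0.435 and 0.307 to 0.534 in the peritoneum, and 0.437 to 0.566, 0.118 to 0.226, 0.0745 to 0.213, 0.449 to 0.626 and 0.288 to 0.380 by vein. Changed genera were 46 to 56, 4 to 4, 15 to 23, 52 to 62 and 20 to 42 by mouth, 14 to 49, 1 to 3, 0 to 0, 17 to 29 and 0 to 40 in the peritoneum, and 35 to 53, 0 to 4, 0 to 2, 36 to 47 and 38 to 51 by vein, and within-mouse calls 8 to 10. For intraperitoneal ampicillin the lone sample left is assumed to vary like the other groups. Depth limits what 0 means, as recovered reads ran down to 30 at day 4, and the limits cover counting error alone, since PCR reads are not independent molecules. Alternatives planned for counts were not run, since the table does not hold counts.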

Other observations

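The split of the Shannon index into a part between families and a part within families was computed only after the fall in family level differences was seen, and it was not tested. Oral PBS samples had 1.16 between families and 1.84 within families. Oral vancomycin samples had 1.18 and 0.0651, oral ampicillin samples 0.711 and 0.0737, oral mix samples 0.882 and 0.408 and oral neomycin samples 1.24 and 1.20. Intravenous PBS samples had 0.923 and 1.96, intravenous ampicillin samples 0.898 and 1.17, intravenous vancomycin samples 1.25 and 0.604 and intravenous mix samples 1.18 and 0.570. Intraperitoneal PBS samples had 1.12 and 1.84, against 1.20 and 0.968 with vancomycin.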
